A study of Mus musculus with 2 samples.

How the data were processed

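MicroRNA sequencing was done on 2 libraries of small RNA from hearts of mouse embryos (strain B6NCrl) at embryonic day 10.5. Each library came from its own pool of embryos of mixed sex, 69 embryos for replicate 1 and 51 for replicate 2, and the labels call the libraries biological replicates. The labels give 1 group only, so no comparison between conditions, tissues or ages was made, and every comparison is between genes within the tissue or between the 2 replicate libraries. With 1 library per pool, the spread between the libraries holds the differences of the pools and of library preparation together.

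The values are read counts per gene as deposited by the authors, with no normalization. Each library's counts came from its own alignment file against mouse assembly mm10 with GENCODE M4 gene models, per the README files deposited with the libraries. The aligner, its settings and the adapter trimming are not given in the sources used here. The tables hold 1973 microRNA genes (hairpins, not mature arms), named by Ensembl identifier, and for each gene a count over both strands, a count on the gene's own strand and a count on the opposite strand. The count over both strands equalled the sum of the strand counts for all 1973 genes, and the 3 columns of a library summed to the same total, 10042860 reads in replicate 1 and 10996991 in replicate 2. Rows that name no gene were left out of library sizes and tests. They held 26.3% and 25.5% of reads as unmapped, 23.3% and 23.5% as mapped to several places, and, for the own-strand column, 8.98% and 7.41% as mapped outside the listed genes, in replicates 1 and 2. Reads mapped to several places were entered in a row of their own and not to genes, so genes with near-identical copies are undercounted to an unknown extent. Such genes were marked where the hairpin shares a stretch of 20 or more bases with another annotated microRNA, which held for 923 listed genes.

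Own-strand counts were used throughout, 4163656 in replicate 1 and 4789068 in replicate 2. Levels are own-strand counts scaled to the same total in each library, as CPM of all own-strand gene counts, given as mean and SD over n = 2 libraries. A count of 0 allows up to 3 counts, which is 0.721 CPM in replicate 1 and 0.626 CPM in replicate 2. Exact (Clopper-Pearson) 95% intervals of shares and ratios were computed with scipy 1.17.1. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene symbols, positions and overlapping genes came from GENCODE M21, which is on the same mm10 (GRCm38) assembly. Of the 1973 identifiers, 1894 matched by stable identifier, and none of the 79 others had more than 2 counts in a library.

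For the replicate comparison, genes with at least 10 counts in at least 1 library were tested with an exact two-sided conditional binomial test, given library sizes scaled by TMM (edgeR 4.0.16), with Benjamini-Hochberg adjustment at 0.05. This test compares the 2 libraries and not conditions, and it asks whether a difference exceeds counting error. The log2 ratios add a prior count of 0.5. The size of replicate error was estimated as edgeR's common dispersion with an intercept-only design, which leaves 1 residual degree of freedom. For 21 gene lists fixed before the data were examined, the summed share of counts was computed per library, and for the 20 with at least 3 tested members the median log2 ratio of replicate 2 over replicate 1 was placed among 10000 random lists of the same size matched on expression in 10 bins. Members of a list often lie in a single cluster and are not independent, so a percentile describes these libraries and is not a p-value. Neighbouring genes on the same strand at most 10 kb apart were compared with partners redrawn 10000 times from the same expression bin.

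The genes named are the 20 with the highest mean CPM, the 3 highest members of each list, all members of the striated muscle list, and the 5 with the largest fold each way among genes past the binomial test with at least 100 counts in the 2 libraries together. This rule, the lists, the tests and the alternatives were set before the data were examined, and the few added later are named in the closing section. Poisson counts without replicate spread were simulated from the 424 tested genes with 200 changed and tested with known library totals. On these, the binomial test recovered 58.0% of 1.25-fold, 80.0% of 1.5-fold, 88.0% of 2-fold and 94.0% of 4-fold changes. It called 2.68% of unchanged genes. These rates cover counting error only and do not speak to replicate spread or to the choice of scaling. The dispersion estimate returned 9.59%, 29.7% and 61.4% for simulated coefficients of variation of 10%, 30% and 60%. The alternatives were the count over both strands, DESeq2 1.42.0 size factors or total counts as scaling, no filter on low counts, other pseudocounts, each replicate alone, leaving out the most abundant gene, and neighbours up to 50 kb apart. Signal tracks were not used here.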

Results

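Small RNA of embryonic day 10.5 mouse heart was profiled in 2 libraries, each from a separate pool of dissected hearts (69 and 51 embryos). Of 1973 listed microRNA genes, 381 had at least 10 own-strand counts in both libraries, and 1233 (62.5%) had no count in either. The libraries held 4163656 and 4789068 own-strand gene counts. The design has 1 group. The data answer which listed genes hold the microRNA counts of the heart at this age. They also answer how the counted levels of gene groups compare with each other, and how closely the pools agree.

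A small number of genes dominated the own-strand gene counts. These counts leave out reads mapped to several places (23.3% and 23.5% of reads) and microRNAs not among the listed identifiers, such as Mir378a. Shares and ranks therefore describe the counted genes only. Mir335 was the most abundant, with 151298 ± 16851 CPM (SD, n = 2), and exceeded the next gene, Mir143, 2.02-fold in replicate 1 and 1.92-fold in replicate 2. Mir335 (ENSMUSG00000065501.1) lies at chromosome 6, 30741299 to 30741396 (mm10), in an intron of Mest, an imprinted gene expressed from the paternal allele. Mir143 of the Mir143-Mir145 locus, known from smooth muscle, had 76938 ± 11418 CPM (ENSMUSG00000065445.2; chromosome 18, 61649196 to 61649258, in no other annotated gene). Mir322 of the X-linked Mir322-Mir503 cluster had 56004 ± 9278 CPM (ENSMUSG00000065418.1; chromosome X, 53054255 to 53054349). Mir126a, the endothelial microRNA within Egfl7, had 54405 ± 1554 CPM (ENSMUSG00000065540.1; chromosome 2, 26591357 to 26591429, overlapping an Egfl7 exon). Mir17 of the Mir17-92 host transcript had 37110 ± 13467 CPM (ENSMUSG00000065508.1; chromosome 14, 115043671 to 115043754, within an exon of Mir17hg). Mir208b, which lies in an intron of the myosin heavy chain gene Myh7, had 35502 ± 20457 CPM (ENSMUSG00000077928.1; chromosome 14, 54975700 to 54975776).

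The 10 most abundant genes held 53.3% ± 6.10 of own-strand counts (SD, n = 2). Besides those named above, they were Mir99a with 35927 ± 749 CPM, Mir26b with 30577 ± 40.3, Mir351 with 28735 ± 13279 and Mir30e with 26887 ± 868. The share was 49.0% in replicate 1 (95% exact interval 48.98 to 49.07) and 57.7% in replicate 2 (57.61 to 57.70), so the difference between the libraries exceeded counting error. At least 10000 CPM in both libraries was reached by 18 genes, at least 1000 CPM by 79 and at least 100 CPM by 195. The remaining genes of the 20 most abundant ran from Mir21a with 17824 ± 2123 CPM down to Mir23b with 11172 ± 1198 CPM. They were Mir21a, Mir130a, Mir99b, Mir23a, Mir208a, Mir30a, Mir20a, Mir652, Mir411 and Mir23b. Mir23a and Mir23b share a stretch of at least 20 bases, as do Mir411 and Mir758, so part of their reads could have been left uncounted.

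**Figure D1:**
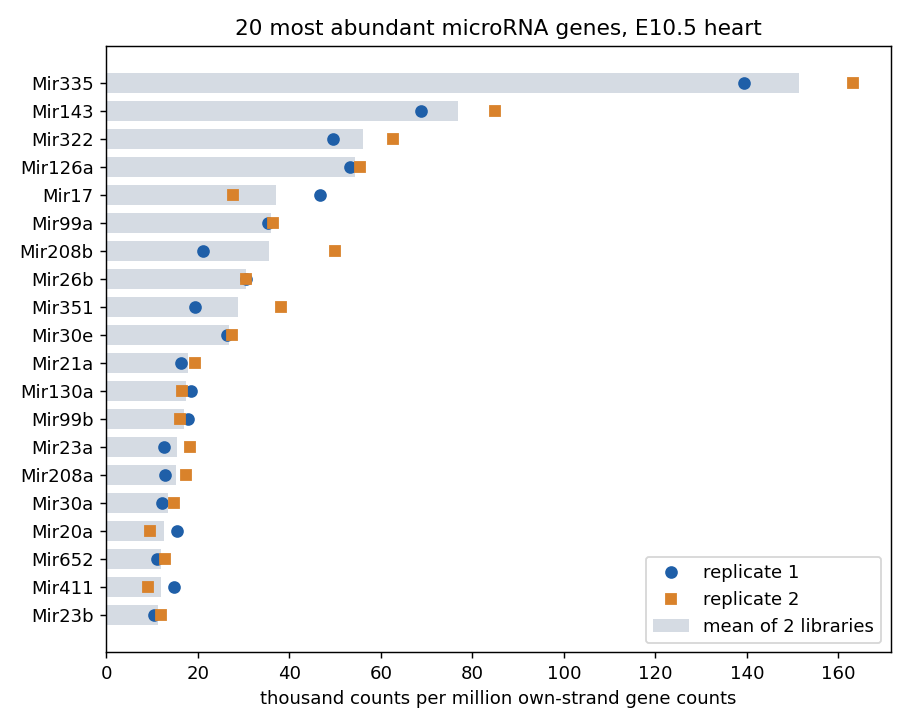
CPM of own-strand gene counts (x axis, divided by 1000) of the 20 most abundant microRNA genes (y axis) in E10.5 heart. Grey bars are means of the 2 libraries, circles replicate 1 and squares replicate 2; Mir335 exceeds every other gene in both libraries, and Mir208b and Mir351 lie furthest apart in proportion, at 2.87-fold and 2.38-fold after TMM scaling.

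Striated muscle microRNA genes made up 5.19% ± 2.43 of counts (SD, n = 2), with 3.48% in replicate 1 and 6.91% in replicate 2. Nearly all of it, as counted, came from microRNAs within myosin heavy chain introns. These were Mir208b (Myh7), Mir208a with 15135 ± 3251 CPM (chromosome 14, 54949060 to 54949142, in Myh6) and Mir499 with 1257 ± 551 CPM (chromosome 2, 155622880 to 155622958, in Myh7b). Mir208b exceeded Mir208a 1.64-fold in replicate 1 and 2.87-fold in replicate 2. The skeletal muscle gene Mir206 had 12.7 ± 3.15 CPM and Mir133b 1.81 ± 0.495 CPM. Mir1a-1, Mir133a-1 and Mir133a-2, known as abundant microRNAs of heart muscle, had 3.61 ± 0.672, 1.93 ± 1.70 and 0.224 ± 0.0221 CPM, and Mir1b had 19 and 26 counts. Mir1a-1 shares its sequence stretch with Mir1a-2, which is not among the listed identifiers, and Mir133a-1 and Mir133a-2 share theirs with each other and with Mir133b, so these counts do not measure the levels of miR-1 and miR-133a. The share of the striated muscle list is therefore a lower limit, and its make-up is uncertain.

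Among the other lists, the Mir322-Mir503 cluster held the highest mean share, 8.95% ± 2.32, followed by the imprinted Dlk1-Dio3 cluster with 8.33% ± 3.15 and the Mir143-Mir145 genes with 7.79% ± 1.15. The Mir17-92 cluster and its paralogs, known from proliferating cells, held 7.71% ± 2.54, the Mir99-Mir100-Mir125 genes 6.30% ± 0.279, the endothelial list 5.45% ± 0.153 and the Mir30 family 4.90% ± 0.413. The order of these lists differed between the libraries. Dlk1-Dio3 led in replicate 1 with 10.6% and the Mir322-Mir503 cluster in replicate 2 with 10.6%, so their means cannot be ranked at n = 2. Mir409, Mir376a, Mir299a and Mir380 of the Dlk1-Dio3 list are not among the listed identifiers. Reads at their loci lay on the strand opposite to listed genes, with 10693 CPM of counts over both strands at Mir409. The Dlk1-Dio3 share is therefore a lower limit. The Mir23-Mir27-Mir24 clusters held 2.82% ± 0.516 and the mesenchymal list 2.30% ± 0.0310, of which Mir21a was the largest member and Mir214 had 4298 ± 2381 CPM. Of 9 listed mesenchymal genes 6 have a near-identical copy, so the mesenchymal share is uncertain despite its small SD. The pluripotency clusters still held 2.62% ± 0.439, with Mir302a at 9393 ± 1559, Mir302b at 7193 ± 991 and Mir302d at 7041 ± 1350 CPM. Mir302a and Mir302b are near-identical copies, and without genes that have a copy this share was 1.05% of the remaining counts. All 5 listed Mir23-Mir27-Mir24 genes have a near-identical copy, so both shares are uncertain. The let-7 family, which accumulates as cells differentiate, held 1.31% ± 0.656 (0.845% in replicate 1 and 1.77% in replicate 2), led by Mirlet7g with 6544 ± 2600 CPM. Several let-7 genes are near-identical copies, so their counts are lower limits and the share is uncertain. The Mir15-Mir16 family held 0.664% ± 0.0881, led by Mir15a with 3025 ± 533 CPM.

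The Hox-cluster, blood, Sfmbt2 repeat and other-tissue lists held smaller shares than the striated muscle list in both libraries. The Hox-cluster microRNAs held 0.997% ± 1.12, with 1.79% in replicate 1 and 0.205% in replicate 2. The epithelial list held 0.458% ± 0.352 (0.707% and 0.209%), the Mir183-Mir96-Mir182 cluster of sensory organs 0.366% ± 0.287 (0.569% and 0.163%) and the liver and gut list 0.182% ± 0.216 (0.335% and 0.0293%). The Sfmbt2 repeat cluster of extraembryonic tissue held 0.450% ± 0.0591. Red blood cell microRNAs held 0.144% ± 0.0391, of which Mir451a had 1228 ± 397 CPM, Mir144 111 ± 12.0 and Mir486 97.1 ± 5.57. The leukocyte list held 0.0428% ± 0.00963, with Mir155 at 214 ± 0.342 and Mir223 at 179 ± 86.3 CPM. Mir142, a main leukocyte microRNA, is not among the listed identifiers, and with counts over both strands, which take in reads at its locus, this list held 0.245%. The neural list held 0.0417% ± 0.00533, with Mir138-2 at 135 ± 0.696 CPM. Of 15 listed neural genes 13 have a near-identical copy, as do 67 of 69 Sfmbt2 repeat genes, so their counts are lower limits and these shares are uncertain.

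Within each library, striated muscle counts exceeded those of every one of these 8 lists. The log2 ratio of the muscle list to the other list averaged 3.02 ± 2.91 for Hox, 3.67 ± 1.94 for epithelial, 3.45 ± 0.89 for the Sfmbt2 repeats, 4.01 ± 1.98 for the sensory cluster and 5.63 ± 3.19 for liver (SD, n = 2). It averaged 5.12 ± 0.30 for erythroid, 6.86 ± 1.03 for leukocyte (4.29 with counts over both strands) and 6.88 ± 0.89 for neural genes. The lowest single value was 0.96, for Hox in replicate 1. With 2 libraries the smallest two-sided p an exact sign-flip test can give is 0.5, so these ratios were not tested against 0.

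**Figure D2:**
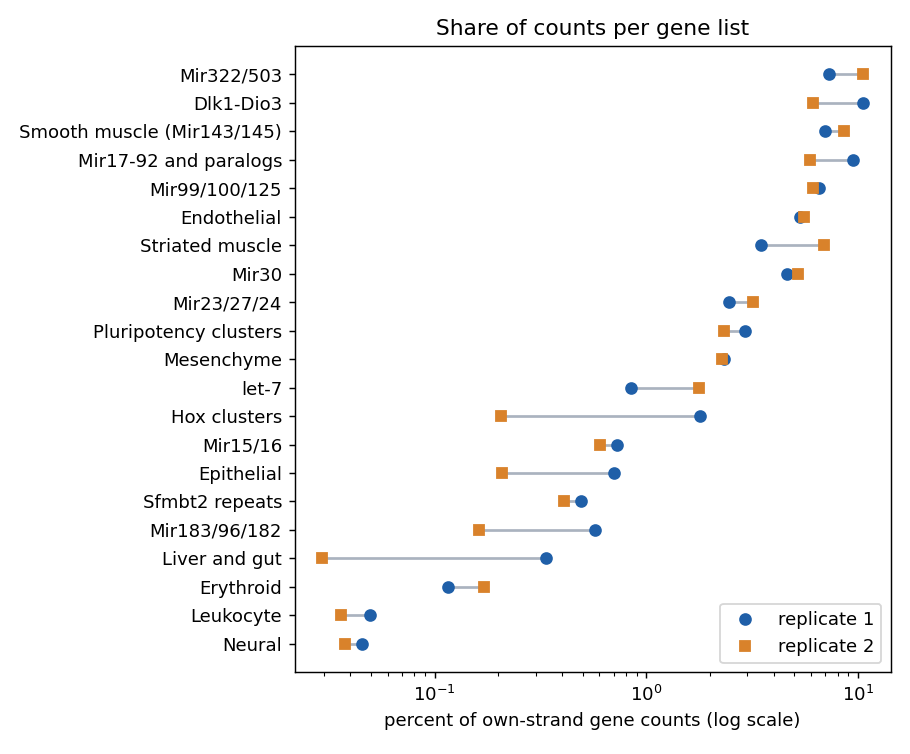
Percent of own-strand gene counts (x axis, log scale) held by each of 21 gene lists (y axis) in replicate 1 (circles) and replicate 2 (squares) of E10.5 heart, with a line joining the libraries. The Hox list (1.79% against 0.205%) and the liver and gut list (0.335% against 0.0293%) are the most separated between the libraries.

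The replicate libraries ranked genes alike but differed in the levels of particular gene groups. Across the 381 detected genes, log2(CPM + 1) correlated with Pearson r = 0.979 and Spearman rho = 0.976, a relation across genes, which are not independent replicates. The common biological coefficient of variation was 37.2%, against 18.7% from the median gene-wise dispersion of DESeq2, and the median of the 424 tested genes differed 1.38-fold between the libraries after TMM scaling. A chi-square over genes of 354100 with 460 degrees of freedom showed that the libraries differed beyond sampling noise and are not a single library deposited again. Of 424 tested genes, 261 (61.6%) passed the exact binomial test, 129 higher and 132 lower in replicate 2. With total counts as the scaling, which lowers the median of all tested genes by 0.27 on the log2 scale, 262 passed, 66 higher and 196 lower. Of the TMM calls, 198 kept their call and direction under total counts.

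Genes higher in replicate 2 included those of heart muscle, the let-7 family and the Mir322-Mir503 cluster. Striated muscle genes had a median log2 ratio of 0.72 (percentile 98.8 among random lists), with 4 of 7 tested members higher and 0 lower. These were Mir208b at 1.52 (95% exact interval 1.51 to 1.53), Mir499 at 1.20 (1.14 to 1.26), Mir208a at 0.72 (0.70 to 0.73) and Mir133a-1, on 3 and 15 counts. Mir206, Mir1b and Mir1a-1 did not pass. All 9 tested let-7 family genes were higher, with a median of 1.14 (percentile 100), among them Mirlet7b at 2.34, Mirlet7i at 1.63, Mirlet7d at 1.59 and Mirlet7g at 1.11. All 7 genes of the Mir322-Mir503 cluster were higher, with a median of 0.66 (percentile 99.7), led by Mir351, which was 2.38-fold higher, with Mir322 at 0.61 and Mir503 at 0.46. In the same comparison all 7 tested epithelial and all 5 tested Hox genes were lower, while 2 of 3 erythroid genes were higher and the 9 neural genes went both ways. With total counts as the scaling, 8 of the 9 let-7 genes, 4 muscle genes and 7 Mir322-Mir503 genes were higher. The call counts adjusted over the list alone were 4, 9 and 7.

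Genes lower in replicate 2 included those of the Hox clusters, of liver, epithelium and sensory organs, of the Mir17-92 clusters and of the Dlk1-Dio3 locus. All 5 tested Hox-cluster genes were lower, with a median log2 ratio of -2.62 (percentile 0.055). Mir10b was 10.8-fold lower (95% exact interval of the log2 ratio -3.50 to -3.38), and Mir10a was 6.86-fold lower (-2.82 to -2.74). Mir10b lies in an intron of Hoxd3 and Hoxd4 at chromosome 2, 74726070 to 74726137, and Mir10a at chromosome 11, 96317165 to 96317274. Mir196b, overlapping a Hoxa9 exon, was 3.65-fold lower. In the liver and gut list, with a median of -1.28 (percentile 0.365), 3 genes were lower and 1 higher. Mir122, the main liver microRNA, was 14.6-fold lower (-3.97 to -3.76; 3078 CPM in replicate 1 and 175 in replicate 2), Mir192 2.52-fold and Mir194-2 2.34-fold lower. The gene of this list that was higher was Mir194-1, named after its value was seen, with a log2 ratio of 1.42. Mir194-1 and Mir194-2 are near-identical copies.

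All 7 epithelial genes were lower, with a median of -1.60 (percentile 0), among them Mir200c at -1.74, Mir429 at -1.58 and Mir205 at -1.19. Mir182, Mir96 and Mir183 of the sensory-organ cluster were lower at -1.55, -1.51 and -1.50 (percentile 2.02). The percentile of this list was 2.82 when members and random lists were limited to genes with at least 100 counts, a setting added later. Of the Mir17-92 cluster and paralogs, 14 of 15 tested genes were lower, with a median of -0.48 (percentile 1.28), including Mir17 at -0.48, Mir20a at -0.40 and Mir93 at -0.18. Of the Dlk1-Dio3 genes, 38 of 40 were lower, with a median of -0.59 (percentile 0), including Mir431 at -0.53, Mir411 at -0.41 and Mir487b at -0.37. The call counts adjusted over the list alone were 5 for Hox, 4 for liver, 7 for epithelial, 3 for sensory, 15 for the Mir17-92 paralogs and 38 for Dlk1-Dio3. The medians of these 6 lists and of the 3 higher lists kept their sign under every scaling tried.

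The other 11 lists with a percentile lay in the central 95% of random lists. All 6 Mir30 genes and all 5 Mir23-Mir27-Mir24 genes were higher in replicate 2, with medians of 0.49 and 0.49 and percentiles of 95.8 and 95.1. With total counts as the scaling, 4 of the Mir30 and 3 of the Mir23-Mir27-Mir24 genes were higher, and Mir27b moved from 0.25 to -0.03. In the erythroid list Mir451a was higher at 0.95 and Mir486 at 0.39, while Mir144 did not pass at 0.06. Under total counts Mir486 did not pass, and Mir144 was lower at -0.22. In the leukocyte list Mir223 was lower at -0.75 and Mir146 at -0.55, and Mir155 was higher at 0.28. Under total counts Mir155 did not pass and 0 leukocyte genes were higher. The neural list had a median of -0.25 (percentile 13.5), with 2 of 9 genes higher, 3 lower and 4 not passing. Mir138-2 was higher at 0.26 (-0.01 under total counts, not passing), Mir128-1 higher at 0.39 (0.11, not passing) and Mir138-1 lower at -0.44. Under total counts 0 neural genes were higher and 5 lower. The pluripotency clusters had a median of -0.10 with 6 of 12 genes lower, among them Mir302d at -0.12 and Mir302a at -0.07, while Mir302b did not pass at -0.01. Under total counts 10 of them were lower, Mir302b among them. The Sfmbt2 repeats had a median of -0.10, with 2 of 10 genes higher (Mir467d at 0.06 and Mir467e at 0.09) and 1 lower (Mir467c at -0.10). Under total counts 0 were higher and 8 lower, with Mir467d at -0.21 and Mir467e at -0.18.

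In the endothelial list Mir126a was higher at 0.33 (0.06 under total counts), Mir218-2 lower at -0.63, and Mir218-1 did not pass at 0.50. In the mesenchymal list Mir29a was higher at 0.74 and Mir21a at 0.52, and Mir214 was lower at -0.92. In the Mir99-Mir100-Mir125 list Mir99a was higher at 0.32 and Mir99b at 0.14, and Mir100 was lower at -0.47. The direction of this list turned with the scaling, with a median of 0.15, and of -0.12 under total counts, where Mir99b was lower at -0.14. In the Mir15-Mir16 list Mir15b was higher at 0.15 (lower at -0.12 under total counts), Mir15a lower at -0.09, and Mir16-1 did not pass, with a ratio that rounded to 0. Under total counts Mir16-1 was lower at -0.27, and this list had 1 gene higher and 4 lower. The smooth muscle list has 2 tested genes and no percentile, and both were higher, Mir143 at 0.58 and Mir145a at 0.47. Mir145b had no count in either library, which allows up to 0.721 and 0.626 CPM. Outside the lists, the genes with the largest folds were Mir5126 at -3.69, on 142 and 10 counts, Mir375 at -2.67 and Mir7j at 1.70, on 29 and 91 counts.

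**Figure D3:**
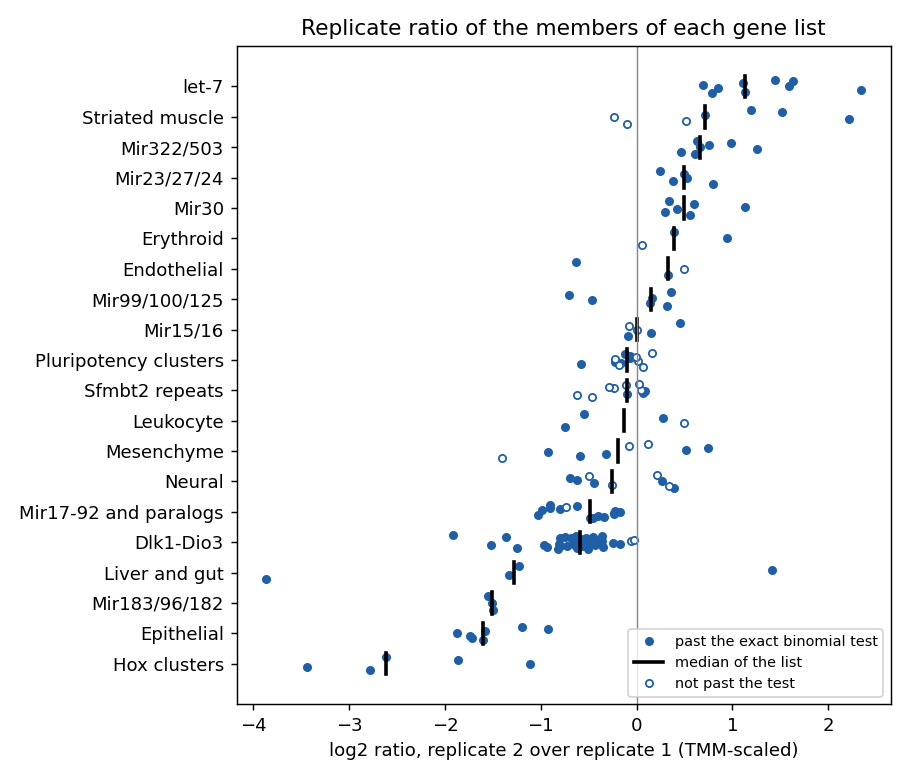
Log2 ratio of replicate 2 over replicate 1 after TMM scaling (x axis) for the tested members of 20 gene lists (y axis). Filled points passed the exact binomial test at an adjusted 0.05, open points did not, and black bars are list medians, which run from -2.62 for the Hox clusters to 1.14 for let-7.

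Neighbouring microRNA genes deviated together. Over 117 pairs of neighbours on the same strand within 10 kb, in 44 clusters, the log2 replicate ratios of the partners differed by a median of 0.20. Partners redrawn from the same expression bin differed by a median of 0.65, and none of 10000 redraws came as low as the observed value (permutation p = 0.0001, the smallest that 10000 redraws can give). The lowest redraw was 0.39. Each partner was redrawn separately, while pairs within a cluster share genes, so the p-value treats dependent pairs as independent.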

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

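The test of this part was chosen after the opposite-strand counts were seen. Counts on the strand opposite to a listed gene were outside the main measurement. They made up 4.46% of gene counts in replicate 1 and 4.58% in replicate 2, and 99.7% of them lay at 9 loci, all far above the 3 counts that an empty locus allows. In mean CPM of the counts over both strands, the opposite-strand signal was 22150 at Gm25301, 10693 at Gm24321, 2512 at Gm25252, 2071 at Gm24083, 2038 at Mir142b, 1970 at Gm25927, 1813 at Mir299b, 1379 at Gm25750 and 430.1 at Mir497b. Own-strand counts at these loci were 23 and 12 at Mir299b, 5 and 1 at Mir497b, and 0 at the others.

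A candidate explanation is a microRNA gene on the other strand whose identifier is not listed. GENCODE M21 has such a gene at 9 of the 9 loci (100%), against 18 of the 380 other detected genes (4.74%). In the order given, they are Mir378a, Mir409, Mir376a, Mir191, Mir142, Mirlet7e, Mir299a, Mir380 and Mir497. The own-strand counts therefore leave out Mir142, an abundant microRNA of blood cells, Mirlet7e, and Mir378a, which by this signal would rank among the 20 most abundant genes. Between replicates, the log2 ratio of the opposite-strand share of all gene counts was 0.85 at the Mir378a locus, -0.59 at Mir142 and -1.02 at Mir409 of the Dlk1-Dio3 cluster. These ratios use total counts as the scaling, so they cannot be set directly beside the TMM-scaled ratios given above. No biological explanation was tested.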

How the results depend on the processing

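The settings without near-identical copies, with members of at least 100 counts and with the 10 most abundant genes left out of the scaling were chosen after seeing the data. The number of genes past the binomial test was 270 with counts over both strands, 262 with DESeq2 size factors, 262 with total counts and 254 without a filter, against 261. Total counts as the scaling lower every ratio by about 0.27, which moved the balance of calls (66 higher, 196 lower) and turned the direction of 8 named genes, to -0.16 for Mir130a, -0.14 for Mir99b, -0.0267 for Mir27b, -0.22 for Mir144, -0.0105 for Mir138-2, -0.21 for Mir467d, -0.18 for Mir467e and -0.12 for Mir15b. It also turned the median of the Mir99-Mir100-Mir125 list, and the Mir15-Mir16 median, close to 0, changed sign between settings. The 9 lists outside the central 95% of random lists kept their direction under total counts and DESeq2 size factors. Leaving the 10 most abundant genes out of the TMM scaling moved no list median by more than 0.000409, so it tests nothing. No paired analysis was possible because the 2 libraries form a single group. Leaving out either replicate gave each list share its value in the other library, furthest apart for Hox (1.79% and 0.205%) and liver (0.335% and 0.0293%). Genes with at least 1 count in both libraries numbered 619, against 381 with at least 10. The median gene-wise dispersion of DESeq2 gave a coefficient of variation of 18.7% against 37.2%, and without a filter the correlation across genes was 0.987. Counting both strands gave 5.20% for the endothelial list, 0.245% for leukocyte (through the opposite-strand counts at Mir142b), 2.19% for mesenchyme and 6.02% for Mir99-Mir100-Mir125, and a log2 ratio of striated muscle to leukocyte of 4.29. With both strands Mir1b passed the test at 1.06, but most of its counts then lay on the opposite strand (65 and 138, against 19 and 26 on its own). Leaving out Mir335 raised shares by construction, to 9.19% for smooth muscle, 6.42% for endothelial, 0.0490% for neural, 3.09% for pluripotency, 0.529% for the Sfmbt2 repeats, 2.71% for mesenchyme, 0.781% for Mir15-Mir16, 7.42% for Mir99-Mir100-Mir125 and 5.78% for Mir30. It cannot move ratios between lists. Leaving out genes with a near-identical copy also took their counts out of the total, so a list that loses few counts rises by construction. As percent of the remaining counts, this gave 5.997% for endothelial, 0% for Mir23-Mir27-Mir24, 0.00386% for neural, 1.05% for pluripotency, 8.57e-05% for the Sfmbt2 repeats, 2.48% for mesenchyme, 0.502% for Mir15-Mir16, 6.85% for Mir99-Mir100-Mir125 and 5.38% for Mir30. With members of at least 100 counts, the sensory cluster kept its median of -1.51 but moved from percentile 2.02 to 2.82, since the random lists changed. Multiply mapped reads, at 23.3% and 23.5% of reads, limit what can be said of genes with copies, and depth limits detection to 0.721 and 0.626 CPM in replicates 1 and 2.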

Other observations

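The genes of this paragraph, and the comparisons below of abundant genes, tissue share, dilution, neighbouring tissue and stage, were chosen after the results were seen. Outside the fixed lists, Mir335, in an intron of Mest, and Mir483, in an intron of Igf2, were higher in replicate 2 by 0.50 and 0.50 on the log2 scale. Both host genes are imprinted and expressed from the paternal allele. Mir22 was higher at 0.67, Mir107, in an intron of Pank1 and with near-identical copies, at 0.65, and Mir210, known for its rise under low oxygen, at 0.50. Lower in replicate 2 were Mir375, known from endocrine pancreas and pituitary, at -2.67, Mir92b at -0.83 and Mir139 at -0.65. With total counts as the scaling, each of these ratios is about 0.27 lower and none changes direction.

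A pattern across lists is that 18 of 19 tested Hox, liver, epithelial and sensory-cluster genes were lower in replicate 2, with a median log2 ratio of -1.58. These 4 lists were picked after their ratios were seen, and several of their genes lie in shared clusters. Of all 424 tested genes, 132 were lower. Elsewhere, 3 of 9 neural, 2 of 4 leukocyte, 0 of 3 erythroid and 1 of 10 Sfmbt2 repeat genes were lower. With total counts, the 19 genes had a median of -1.86 and the 395 other tested genes outside the 10 most abundant -0.28. The difference of -1.58 cannot decide whether a few abundant genes took most of the counts. The lists were picked for low ratios and a scaling shifts all genes alike, so this outcome was set beforehand. The GC content of the hairpins is argued against, since the median of the 19 genes was -1.59 after a lowess trend on GC was removed. Whether a lower share of heart raised all other tissues alike in replicate 1 cannot be decided here. The epithelial and sensory lists were picked for their low ratios, and 13 of 15 listed neural genes have a near-identical copy. Epithelial genes ran from -1.88 to -0.92 and sensory genes from -1.55 to -1.50, while neural genes ran from -0.70 to 0.39. Liver genes ran from -3.87 to 1.42, across both. With each genomic cluster as 1 unit, 54.6% of the variance of the log2 ratio lay between the 8 lists named above (permutation test, p = 0.00996, 30 units). That result rests on the Hox list, which is not a list of tissue markers, and without it p was 0.192 (35.9%, 25 units). An unequal rise of other tissues was not tested. Open are a particular neighbouring tissue in replicate 1 (Mir122 at -3.87) or a later stage of the embryos in replicate 2 (let-7 median 1.14), which cannot be told apart with 1 pool per library. Dilution of heart RNA as the whole cause of the higher Mir208a, Mir208b and Mir499 also stays undecided. Their log2 ratios span 0.81, under the 95th percentile of 0.99 over the 117 neighbour pairs. That span is above the 0.78 of the 62 pairs with at least 1000 counts per gene. A span over 3 genes is also an unlike measure to a difference within a pair, so neither percentile decides.

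The other pattern is the very low count of Mir1a-1, Mir133a-1 and Mir133a-2. A candidate explanation is that reads shared between near-identical copies were left out of the counts. Among let-7 genes and microRNA genes numbered up to 500, the 148 that share a stretch of 20 or more bases with another microRNA had a median of 1.89 CPM and the 203 others 304.1 CPM, a ratio of 0.00622 (two-sided permutation test, p = 2e-05, the smallest that 100000 permutations can give). Without the Sfmbt2 repeat genes, the ratio was 0.0764, with 101 genes that have a copy. Genes with copies differ from the others in more than their copies, so low expression of some of them is not excluded, and no biological explanation was tested.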
